A study of Homo sapiens with 3 samples.

How the data were processed

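Gene expression was measured by RNA sequencing in MCF-7 cells, an established human line of estrogen receptor-positive breast cancer. Per the labels, the cells expressed an empty vector, the cyclin-dependent kinase CDK6, or the substituted form CDK6-D224Y, with 1 library in each of the 3 groups. Total RNA was made into libraries with the KAPA mRNA HyperPrep kit, per the labels' protocols, which captures RNA with a poly(A) tail. How the constructs were delivered, how long they were expressed and whether cells were selected are not given in the sources used here.

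The authors deposited a single table of raw read counts per Ensembl gene, with 58884 gene rows and a column for each library. The counts are whole numbers, were not normalized, and their totals differ between libraries. Per the submitters' processing notes, the tools were Trimmomatic, which trims adapters and low-quality bases, the spliced aligner HISAT2 2.1.0 and the read counter featureCounts 2.0.0, with the genome build GRCh38. The annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads of near-identical genes, such as the pair IFNL2 and IFNL3, HCAR2 and HCAR3, the HLA genes and the histone genes, could therefore have been divided between copies or dropped, and reads of overlapping genes on opposite strands cannot be told apart. Counts of CDK6 add the transcripts of the construct to those of the cell's own gene.

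The table names its columns pCDH, CDK6 and CDK6_D224Y. The pCDH column was taken as the vector library, because pCDH is a family of lentiviral expression vectors and the vector sample is the only one whose labels name no expressed protein. The labels themselves do not print that name. The table had 0 other columns.

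Of the gene rows, 58611 matched GENCODE release 29 by identifier, 265 were named only from a table of gene names, and 8 had no symbol. Coordinates are those of GENCODE release 29 on GRCh38, counted from 1, and those of 18S genes are from RefSeq on the same build.

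Total counts were 17501717 in the vector library, 17650497 in the CDK6 library and 16726803 in the CDK6-D224Y library. Counts were scaled to a library of 1000000 counts (CPM) with the trimmed mean of M-values (TMM) from edgeR 4.0.16 in R 4.3.3. The factors were 0.9999, 0.9991 and 1.001 in the same order. A count of 3, the level that a count of 0 allows, equals 0.171, 0.170 and 0.179 CPM. Genes with a mean of at least 1 CPM over the 3 libraries formed the expressed set of 13609 genes.

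With 1 library per group there are no replicates, so no test across conditions was made and no p-value is given. Differences have no replicate check. For each gene the log2 ratio of 2 libraries was computed with a prior count of 0.5 in each, with the exact conditional binomial (Clopper-Pearson) 95% interval of the ratio of the counts. These intervals cover counting error only, and reads are not independent molecules, since no molecular identifiers are stated. A gene was described as past the size rule when the libraries differed by at least 2-fold and the bound of the interval nearest to no difference lay at 1.5-fold or more. The computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for the figures.

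The 3 pairs of libraries were compared in turn. The gene lists, 21 in all, the rule for the genes named and the alternatives were written before the data were examined. For each list with at least 3 expressed members, the median log2 ratio was set beside the medians of 10000 random lists of the same size drawn from 20 bins of matched mean expression. A list at a percentile under 2.5 or over 97.5 is said to stand apart in these libraries, which describes the libraries and is not a test, since members of a list move together. Counting intervals of medians come from 100 Poisson resamples. Genes were named when they were CDK6, CDK4, YWHAB, RB1, CCND1 or ESR1, when they were among the 10 higher or 10 lower genes with the farthest nearer bound in a comparison against vector (5 and 5 for CDK6-D224Y against CDK6), when they were among the 2 to 4 expressed members of a list with the largest absolute log2 ratio, or when they were past the size rule in opposite directions in the comparisons against vector. Pseudogenes and genes with clone names were passed over in the rankings. Other genes named were chosen after values were seen: B2M, HLA-DRB1, HIST2H4B, PDZK1 and TFF1 in the report, members of families in the closing section, and FP236383.2, FP671120.3, FP671120.4 and the ribosomal RNA genes beside FP236383.3. The blood cell markers PTPRC, LAPTM5, TYROBP, FCER1G, CD14 and CD3E come from a fixed list and were picked from it for a test before their values were seen.

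Both comparisons against vector share the vector library. Their overlap and correlation are therefore given beside those of simulated unchanged libraries, drawn 20 times around the pooled profile with Poisson counts alone or with an assumed biological coefficient of variation (CV) of 0.1 or 0.2. The scripts were tested on simulated data with 200 genes altered by known folds in a simulated comparison of CDK6 against vector. With Poisson counts, 96% of genes altered 4-fold and 93% of genes altered 3-fold passed the size rule, beside 1 of 13409 unaltered genes. With an assumed CV of 0.1, 6 unaltered genes passed, and with an assumed CV of 0.2, 257 did. The CV between cultures cannot be measured here. In the data 33 genes were past the rule in CDK6 against vector, which argues against a CV of 0.2 in every gene. A lower CV, or one that differs between genes, stays possible. The number of genes past the rule that a repeat of the same culture would give is therefore unknown.

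Alternatives were scaling by total counts, by DESeq2 1.42.0 median-of-ratios size factors and by upper quartiles, a prior count of 5, a filter at 5 CPM or none, counts thinned to the smallest library, intervals widened by an assumed CV of 0.1 or 0.2, other size rules, mitochondrial, ribosomal protein and CDK6 genes left out (124 gene rows), only genes with a symbol, the mean in place of the median over a list, and random lists without matching.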

Results

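Gene expression was profiled in 3 cultures of MCF-7, a luminal, estrogen receptor-positive breast cancer cell line. The cells expressed an empty vector, CDK6, or CDK6 with the substitution D224Y. CDK6 is a kinase that, like its relative CDK4, binds D-type cyclins and phosphorylates the retinoblastoma protein RB1 to allow entry into S phase. The series concerns resistance to drugs that inhibit CDK4 and CDK6 and the 14-3-3 protein YWHAB, a phosphoserine-binding adaptor, and these libraries show what accompanied each form of CDK6 in the transcriptome. The labels name no drug treatment. Each group had 1 library, of 17501717 counts for vector, 17650497 for CDK6 and 16726803 for CDK6-D224Y, and 25441, 25621 and 25190 genes had at least 1 count. No difference below has a replicate check, and the 95% intervals in brackets cover counting error only. Mitochondrial genes held 5.13% of counts in the vector library, 5.10% in the CDK6 library and 4.16% in the CDK6-D224Y library.

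CDK6 itself (ENSG00000105810, chromosome 7, 92604921 to 92836594) was read at 87.9 CPM in the vector library (83.6 to 92.4), at 9759 CPM in the CDK6 library (9713 to 9805) and at 12380.5 CPM in the CDK6-D224Y library (12327 to 12434). Its level was thus 111-fold higher with the CDK6 construct and 141-fold higher with the CDK6-D224Y construct than with vector, as the labels say, and the log2 ratio between the constructs was 0.34 (0.33 to 0.35). YWHAB (ENSG00000166913, chromosome 20, 44885676 to 44908532) stood at 499, 505 and 502 CPM in the vector, CDK6 and CDK6-D224Y libraries, with log2 ratios against vector of 0.02 (-0.02 to 0.06) and 0.01 (-0.03 to 0.05), the latter on the other side of 0 with median-of-ratios scaling. CDK4 was at 95.4, 98.3 and 102 CPM and RB1 at 97.3, 102 and 104 CPM. The cyclin D1 gene CCND1 was at 963 CPM with vector and at 1056 and 1053 CPM with the CDK6 forms, log2 ratios of 0.13 (0.10 to 0.16) and 0.13 (0.10 to 0.16). The estrogen receptor gene ESR1 was at 287, 320 and 358 CPM, with log2 ratios of 0.15 (0.10 to 0.21) and 0.32 (0.26 to 0.37). Apart from CDK6, these genes lay below the size rule in each comparison.

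**Figure D1:**
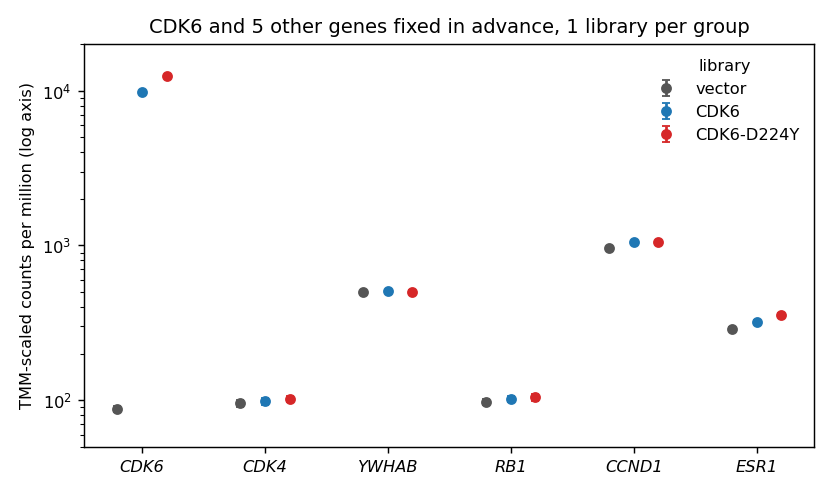
TMM-scaled CPM, on a log axis, of CDK6, CDK4, YWHAB, RB1, CCND1 and ESR1, with points for single libraries and bars for exact Poisson 95% intervals of the count. CDK6 lies at 87.9 CPM with vector and at 9759 and 12380.5 CPM with the constructs, and YWHAB lies between 499 and 505 CPM.

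The comparison of CDK6 with vector asks what accompanied the unsubstituted kinase. The genes lower in the CDK6 library were led by RGS2, a regulator of G protein signalling (3.83-fold lower, log2 ratio -1.94, -2.71 to -1.27), CYP1A1, a cytochrome P450 gene induced through the aryl hydrocarbon receptor (2.86-fold lower, -1.52, -1.80 to -1.25), and IGFBP6, a secreted binding protein of insulin-like growth factors (2.60-fold lower, -1.38, -1.52 to -1.25). The stress keratins KRT6B (-1.75, -2.35 to -1.21) and KRT17 (-1.36, -1.55 to -1.18), the stress-response gene NUPR1 (-1.31, -1.48 to -1.15) and the niacin receptor gene HCAR2 (2.83-fold lower, -1.50) were also lower. So were the type I interferon gene IFNB1, at 75.7 against 166 CPM (2.19-fold lower, -1.13, -1.23 to -1.04), the type III interferon gene IFNL2, at 115 against 244 CPM (-1.08, -1.16 to -1.01), and CP, which encodes ceruloplasmin (-1.32, -1.65 to -1.01). In total 33 of 13609 expressed genes were past the size rule, 8 higher and 25 lower in the CDK6 library, and 5 of them had pseudogene or clone names. Besides CDK6, the higher genes with a symbol were L3MBTL1, a chromatin-binding protein gene (2.61-fold higher, 1.39, 0.71 to 2.15), PROCA1 (2.51-fold higher, 1.33, 0.70 to 2.01), and the mitochondrial transfer RNA genes MT-TR (1.38, 0.66 to 2.20) and MT-TG (1.54, 0.64 to 2.60), each read between 12 and 74 times in a library. MT-TR and MT-TG were no longer past the rule with an assumed CV of 0.1. An interval widened by an assumed CV of 0.2 left 6 genes past the rule, 2 higher and 4 lower.

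By gene list, the NF-kB and inflammatory genes stood farthest from vector in the CDK6 library: 19 of 19 expressed members were lower, with a median log2 ratio of -0.61 (-0.68 to -0.53, percentile 0 of the random lists). Only CXCL8, a neutrophil chemokine, was past the size rule (11.5 CPM with vector, 5.27 with CDK6), and IL6 was at 7.09 and 3.52 CPM. Antigen presentation genes had a median of -0.18 with 23 of 24 members lower, among them CD74, the invariant chain of MHC class II (-0.88), and HLA-DRA (-0.86), and interferon-stimulated genes a median of -0.16 with 27 of 34 lower, among them IFIT2 (-0.74) and OASL (-0.70). No member of these last lists was past the size rule. FOXO target genes (-0.18, 16 of 21 lower), immediate early genes (-0.19, 19 of 26 lower), unfolded protein and amino acid stress genes (-0.12, 20 of 27 lower) and ribosomal protein genes (-0.10, 38 of 40 lower) stood apart on the same side. E2F target genes of DNA replication stood apart on the higher side, with 36 of 36 members above vector and a median of 0.21 (0.17 to 0.23), including DTL (0.35), PRIM1 (0.33) and UHRF1 (0.31), none past the size rule. Smaller medians that also stood apart were those of G1/S regulators (0.07), G2 and mitosis genes (0.08), estrogen response genes (0.08), cholesterol synthesis genes (0.09) and mitochondrially encoded mRNAs (0.08). The 14-3-3 family (0.05, percentile 89.6), luminal identity genes (0.00), basal markers (0.06), fibroblast and mesenchymal markers (-0.07), p53 targets (-0.04), YAP/TEAD targets (-0.06) and hypoxia genes (-0.02) did not stand apart. In all 13 of 20 lists with a median stood apart. Random lists would give 1, but members of these lists move together, so that number does not measure chance here. The estrogen response median was no longer apart with genes of at least 5 CPM (0.04, percentile 95.5). Without expression matching, neither were G1/S regulators (percentile 96.9) and mitochondrially encoded mRNAs (percentile 93.6). Basal markers stood apart on the lower side by the mean over members (-0.16, percentile 0.8).

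The comparison of CDK6-D224Y with vector asks the same of the substituted kinase. Most genes past the size rule were lower with CDK6-D224Y. IGFBP6 (chromosome 12, 53097436 to 53102345) was at 91.1 CPM with vector and 6.75 CPM with CDK6-D224Y (13.4-fold lower, -3.75, -4.04 to -3.48), NUPR1 at 60.8 and 5.20 CPM (11.6-fold lower, -3.54, -3.88 to -3.23), and CD74 (chromosome 5, 150401637 to 150412929) at 57.1 and 4.96 CPM (11.5-fold lower, -3.52, -3.87 to -3.20). The chemokine gene CCL5 (chromosome 17, 35871491 to 35880793) was at 274 and 30.9 CPM (8.88-fold lower, -3.15, -3.29 to -3.02). KRT17 (-3.52, -3.90 to -3.18), CP (-3.17, -3.78 to -2.64) and the planar cell polarity gene VANGL2 (-3.11, -3.60 to -2.67) were lower by 8.61-fold or more. Lower counts set wider bounds for HCAR2 (9 counts with CDK6-D224Y, -3.86, -5.09 to -2.97), KRT6B (4 counts, -4.66, -6.72 to -3.42) and CSAG2 (2 counts against 71, -4.77, -8.16 to -3.18), a cancer-testis gene with a near-identical copy.

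The genes higher with CDK6-D224Y, besides CDK6, were led by CLSTN2, a calsyntenin gene (3.75-fold higher, 1.91, 1.52 to 2.33), MAOB, which encodes monoamine oxidase B (54 against 10 counts, 2.44, 1.51 to 3.64), COL12A1, a fibril-associated collagen gene at 226 against 97.7 CPM (2.32-fold higher, 1.21, 1.13 to 1.30), and NPY1R, a neuropeptide Y receptor gene at 74.7 against 34.0 CPM (2.20-fold higher, 1.14, 0.99 to 1.28). They also included the noncoding RNA gene LINC00052 (1.15, 0.92 to 1.39), DOC2B (1.88, 0.84 to 3.19), PABPC4L (1.52, 0.83 to 2.29), PLEKHB1 (1.12, 0.73 to 1.53) and ANXA6 (1.11, 0.73 to 1.51). Altogether 188 genes were past the size rule, 16 higher and 172 lower, and 17 had pseudogene or clone names. With intervals widened by an assumed CV of 0.2, 87 genes remained in number, 3 higher and 84 lower. PLEKHB1 and ANXA6 were no longer past the rule with an assumed CV of 0.1.

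**Figure D2:**
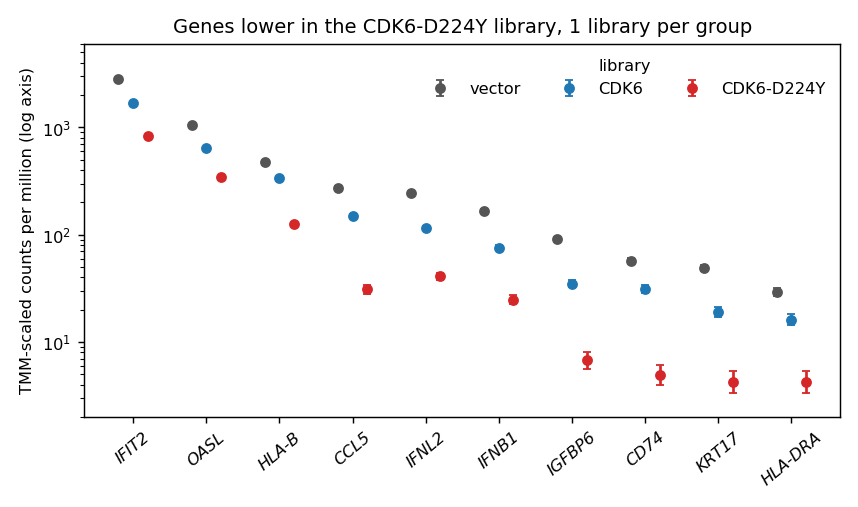
TMM-scaled CPM, on a log axis, of 10 genes lower in the CDK6-D224Y library than in the vector library, picked after their values were seen, with points for single libraries and bars for exact Poisson 95% intervals. For each gene shown the CDK6 library lies between the vector and CDK6-D224Y libraries, as for IFNB1 at 166, 75.7 and 24.7 CPM.

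Among the lists, NF-kB and inflammatory genes had a median log2 ratio of -0.93 in CDK6-D224Y against vector (-0.97 to -0.84, percentile 0), with 19 of 19 members lower and 7 past the size rule, including CCL5, CXCL10 (71.8 and 21.9 CPM), IL6 (7.09 and 2.57 CPM) and TNF (20.2 and 7.53 CPM). Antigen presentation genes had a median of -0.71 (-0.82 to -0.61), with 23 of 24 members lower and 7 past the rule. These comprised the class I genes HLA-B (481 and 127 CPM) and HLA-A (552 and 183 CPM), their partner B2M (1875 and 919 CPM), and, for class II, CD74, HLA-DRA, HLA-DRB1 and the regulator CIITA (B2M and HLA-DRB1 are named here after their values were seen). Interferon-stimulated genes had a median of -0.35 (-0.39 to -0.32), with 27 of 34 lower and 7 past the rule, led by IFIT2 (2848 and 824 CPM) and OASL (1054 and 345 CPM). Other lists on the lower side were FOXO targets (-0.23, 14 of 21 lower, with FBXO32 at -0.88 and TXNIP at -0.80), hypoxia and glycolysis genes (-0.22, 23 of 26 lower, with BNIP3 at -0.69), mitochondrially encoded mRNAs (-0.26, 12 of 13 lower) and immediate early genes (-0.16, 16 of 26 lower, KLF4 and ATF3 past the rule, ATF3 not with a prior count of 5 or an assumed CV of 0.1).

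On the higher side in CDK6-D224Y against vector stood the E2F target genes of DNA replication (0.26, 0.23 to 0.29, with 34 of 36 higher), including GINS4 (0.87), DHFR (0.66) and TYMS (0.60), and the estrogen response genes (0.13, 20 of 29 higher), including KRT13 (1.11), AGR3 (0.77) and MYB (0.70). KRT13 (35 counts with vector, 73 with CDK6-D224Y) and AGR3 (61 and 100 counts) were read few times. The other 9 estrogen response genes were lower, so the list was divided. Among them were PDZK1 (-0.61) and the abundant TFF1 (-0.44, 1454 CPM with vector and 1074 CPM with CDK6-D224Y), both named after their values were seen. No member of these 2 lists was past the size rule. The 14-3-3 family had 7 of 7 members above vector by small amounts, up to 0.21 for YWHAQ but with YWHAB on the lower side under median-of-ratios scaling, and a median of 0.11 that did not stand apart (percentile 94.5). G1/S regulators (0.03), G2 and mitosis genes (-0.05), luminal identity genes (0.01), fibroblast markers (0.17), p53 targets (0.03), YAP/TEAD targets (-0.08), unfolded protein and amino acid stress genes (-0.03), cholesterol synthesis genes (0.06) and ribosomal protein genes (0.02) did not stand apart either. Basal markers had a median of 0.14 (percentile 96.7) but a mean of -0.53 that stood apart on the lower side (percentile 0), because the keratins KRT6B, KRT17 and KRT16 were past the rule on the lower side while 9 of 16 members were higher. Their median stood apart on the higher side with genes of at least 5 CPM (percentile 97.8) and without expression matching (percentile 98.5), as did that of fibroblast markers without matching (percentile 98.2). Of the blood and endothelial markers only ITGAM was expressed, at 2.86, 2.38 and 1.61 CPM in the vector, CDK6 and CDK6-D224Y libraries. In all 9 of 20 lists stood apart.

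**Figure D3:**
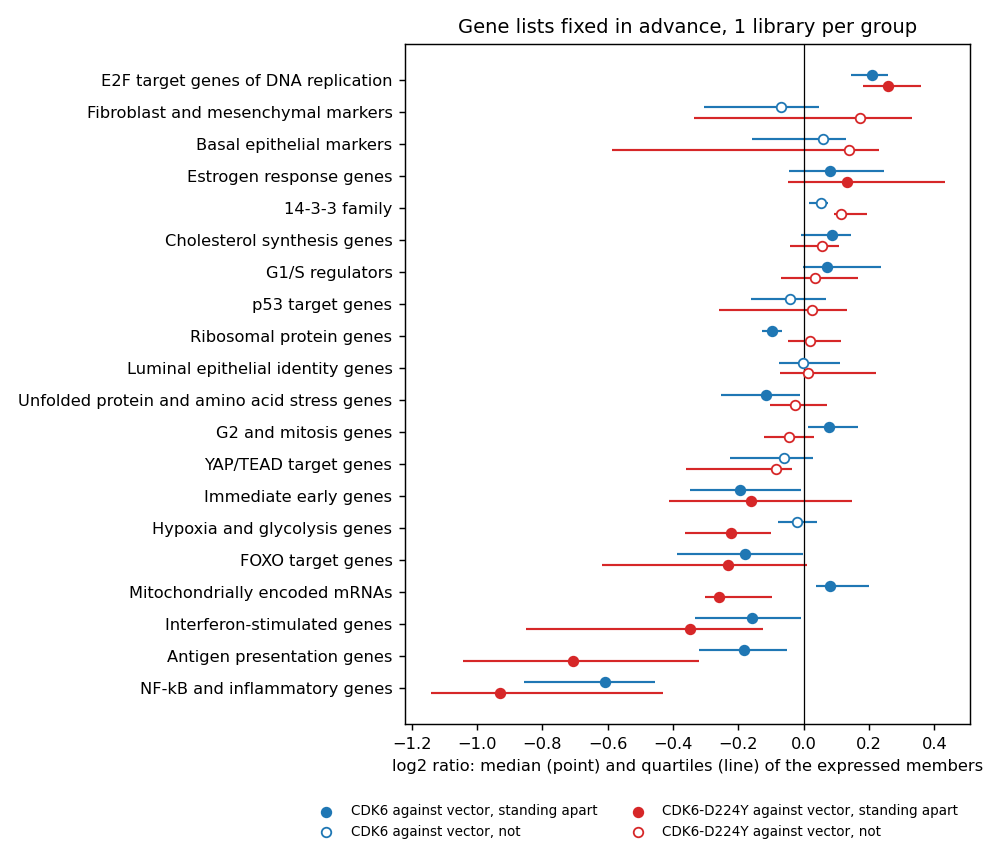
Median log2 ratio (points) and quartiles (lines) of the expressed members of 20 gene lists in CDK6 against vector and CDK6-D224Y against vector, with filled points for medians that stood apart from random lists matched on expression. The NF-kB and inflammatory genes lie lowest at -0.61 and -0.93, and the E2F target genes lie highest at 0.21 and 0.26.

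The comparison of CDK6-D224Y with CDK6 sets the substituted beside the unsubstituted kinase. It also holds any difference between the 2 cultures and in the level of CDK6 itself (log2 ratio 0.34). Lower with CDK6-D224Y were CD74 (6.21-fold, -2.64, -2.99 to -2.31), CCL5 (4.84-fold, -2.27, -2.42 to -2.14), HCP5, a noncoding gene in the MHC region (5.35-fold, -2.42, -2.74 to -2.12), IGFBP6 (5.17-fold, -2.37, -2.68 to -2.08) and CSAG2 (2 counts against 40, -3.94, -7.34 to -2.30). Higher were CLSTN2 (3.10-fold, 1.63, 1.27 to 2.02), MAOB (4.25-fold, 2.09, 1.24 to 3.13), the orphan nuclear receptor gene NR4A3 (2.03-fold, 1.02, 0.67 to 1.38), the collagenase gene MMP13 (2.56-fold, 1.36, 0.67 to 2.12) and HIST2H4A, a histone H4 gene that shares its sequence with HIST2H4B (2.09-fold, 1.06, 0.65 to 1.49). The rule was passed by 72 genes, 11 higher and 61 lower, of which 9 had pseudogene or clone names, and by 37 with an assumed CV of 0.2. NR4A3, MMP13 and HIST2H4A were no longer past it with a CV of 0.1, nor NR4A3 with a prior count of 5 (0.99). HIST2H4B was at 0.32 and not past the rule, and how reads were divided between it and HIST2H4A is not known.

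Antigen presentation genes were again lower with CDK6-D224Y than with CDK6 (median -0.57, 22 of 24 lower, 4 past the rule), as were interferon-stimulated (-0.28, 27 of 34 lower, IFIT2 and IFI44 past the rule) and NF-kB genes (-0.28, 13 of 19 lower, CCL5 past the rule). IFI44 did so only just, at 59.4 against 119 CPM, and not with total counts, thinned counts or a prior count of 5. Mitochondrially encoded mRNAs were lower for 13 of 13 members (-0.34), with MT-ND6 at -0.49. Hypoxia and glycolysis genes (-0.21, 24 of 26 lower) and G2 and mitosis genes (-0.11, 30 of 34 lower) also stood apart on the lower side. On the higher side were ribosomal protein genes (0.13, 38 of 40 higher), estrogen response genes (0.10), unfolded protein and amino acid stress genes (0.07) and E2F targets (0.07, 28 of 36 higher). The stress gene median was no longer apart with genes of at least 5 CPM (percentile 97.3), and neither it (percentile 95.8) nor the E2F median (percentile 96.9) was without expression matching. The 14-3-3 family (0.08), luminal (0.04), basal (0.00) and fibroblast markers (0.15), p53 (-0.02), FOXO (-0.04), YAP/TEAD (0.01), immediate early (-0.06), cholesterol synthesis (-0.04) and G1/S genes (-0.01) did not stand apart. Some of these did under an alternative: basal markers on the lower side by the mean (-0.37, percentile 0.32), FOXO targets lower at 5 CPM (percentile 1.78) and immediate early genes lower without a filter (percentile 2.35). Fibroblast markers stood apart on the higher side with thinned counts (percentile 97.52) and without matching (percentile 98.96).

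The comparisons against vector were then set beside each other, with the CDK6 gene left out. Of the 172 genes lower with CDK6-D224Y, the CDK6 library lay between vector and CDK6-D224Y for 168, with median log2 ratios against vector of -0.65 for CDK6 and -1.59 for CDK6-D224Y. Choosing genes by their ratio favours this order. In simulated unchanged libraries with an assumed CV of 0.2 the remaining library lay between for 86.8% of lower genes chosen in the same way. With a CV of 0.1 it lay between for 87.0%, but only 2.3 such genes arose per simulated set. In 3 fixed lists, brought together after their medians were seen, 59 of 77 interferon-stimulated, antigen presentation and NF-kB genes had the order vector above CDK6 above CDK6-D224Y. That count was not set beside simulated libraries, so it is a description only. The same 20 genes were past the rule on the lower side in both comparisons, and 0 genes on the higher side in both. Simulated unchanged libraries, which also share the vector library, gave 0 and 0 such genes with Poisson counts, 0 and 0.2 with an assumed CV of 0.1, and 9.6 and 24.05 with a CV of 0.2. Independent lists of 25 and 172 among 13608 genes would share 0.316, but that figure leaves out the shared library. The log2 ratios correlated across genes at r = 0.60 with a covariance of 0.0555. The shared vector library alone gave r = 0.50 and a covariance of 0.0175 in simulated unchanged libraries with Poisson counts, 0.0390 with an assumed CV of 0.1 and 0.103 with a CV of 0.2. Genes are not independent replicates, the vector group could not be split, and part of the overlap may come from the shared library.

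**Figure D4:**
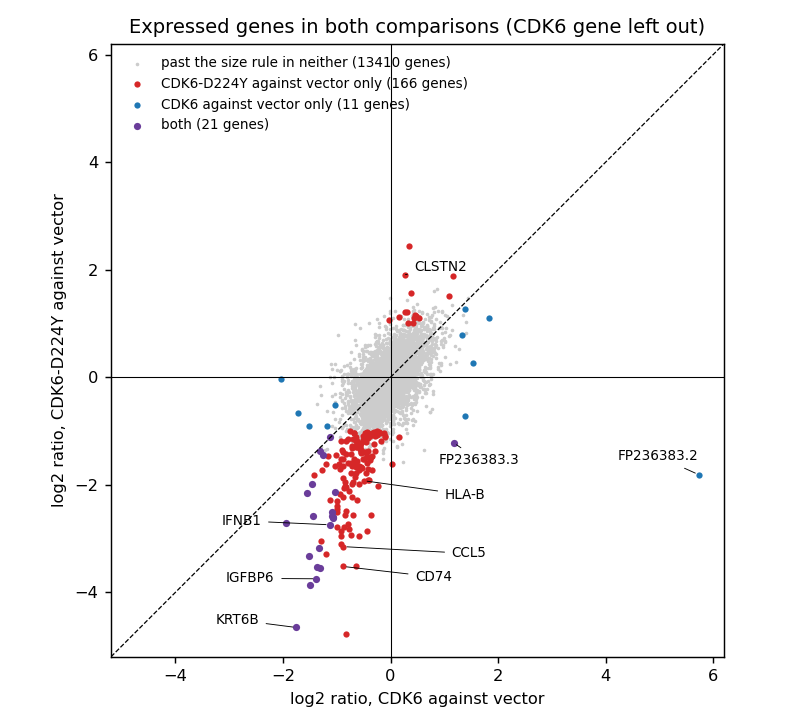
Log2 ratio of each expressed gene in CDK6-D224Y against vector (vertical axis) and in CDK6 against vector (horizontal axis), with the CDK6 gene left out, a dashed line at equal ratios and colours for genes past the size rule. Most marked genes lie in the lower left quadrant below the dashed line, and 20 are past the rule on the lower side in both.

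Over 9279 genes of at least 10 CPM, the variance of the log2 ratios was divided between the libraries. The vector library's part was 0.0295 and that of the CDK6-D224Y library 0.0409, against Poisson parts of 0.0035 and 0.0037. The CDK6 library's part was -0.0049, a negative value that arises when a library lies between the others across genes.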

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

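FP236383.3 was past the size rule in opposite directions in the comparisons against vector, with log2 ratios of 1.17 (0.89 to 1.46) for CDK6 and -1.22 (-1.68 to -0.79) for CDK6-D224Y, and the difference was not tested, since each group has 1 library. Its counts were 149, 339 and 61 in the vector, CDK6 and CDK6-D224Y libraries. The gene model is a noncoding RNA of 923 bp on the minus strand of chromosome 21 (8437629 to 8438551). The models FP236383.2 (8393419 to 8394341), FP671120.3 and FP671120.4 have the same length, with 5, 294 and 1 counts, 0 counts in each library, and 25, 39 and 9 counts. Each of the 4 models lies wholly within an 18S ribosomal RNA gene or pseudogene of RefSeq, such as RNA18SN1 (8436876 to 8438744) for FP236383.3, and ends 1266 to 1272 bp before a 5.8S gene on the plus strand. FP236383.2, FP236383.3 and FP671120.3 differ at 0 bases, so which of them a read was counted for is uncertain. Division of reads among the 4 models does not alter their sum, which had the same order at 179, 672 and 71 counts. The opposite directions thus hold for the summed counts that were kept, while the share of FP236383.3 is not known. Reads that map to several places may also have been dropped, which would alter the sum. The 4 5.8S genes had 10, 4 and 10 counts. Reads of these models may be 18S ribosomal RNA, which capture of poly(A) tails should remove, but the strand of the reads is not known. These positions and sequences were looked up after the counts were seen. A larger carry-over of RNA without a tail into the CDK6 library was tested on 107 small nuclear, small nucleolar, Cajal body and mitochondrial transfer RNAs and similar genes. Their median log2 ratio in the CDK6 library against the mean of the others was 0.093 (-0.05 to 0.23). A median of 0.3 or more would have spoken for carry-over and one under 0.1 against it, and the interval crosses 0.1. That the whole interval had to lie under 0.1 to count against carry-over was set after the value was seen, and MT-TR and MT-TG, which belong to this set, had been seen to be higher before it was formed. The classes moved apart, with 13 of 14 mitochondrial transfer RNAs higher (median 0.63) and small nucleolar and Cajal body RNAs lower (-0.23). The whole interval lay under 0.3, but the classes diverged, so carry-over cannot be told apart from a difference in the cells.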

How the results depend on the processing

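Leaving out replicates, other splits of the samples and a paired analysis were not possible because each group has 1 library. Scaling by total counts, median of ratios or upper quartiles kept the numbers of genes past the size rule at 31 to 35 for CDK6 against vector, 188 for CDK6-D224Y against vector and 71 to 74 for CDK6-D224Y against CDK6. Other settings moved them by their construction. For CDK6 against vector the number was 16 at a mean of 5 CPM, 74 without a filter (29 higher, 45 lower), 6 with an assumed CV of 0.2, 12 with the nearer bound at 2-fold and 349 with a 1.5-fold rule. For CDK6-D224Y against vector it was 87 with a CV of 0.2, 109 with the nearer bound at 2-fold and 788 at 1.5-fold (290 higher, 498 lower). For CDK6-D224Y against CDK6 it was 46 at 5 CPM, 116 without a filter, 37 with a CV of 0.2, 38 with the nearer bound at 2-fold and 455 at 1.5-fold. Under each of these settings lower genes outnumbered higher genes. The CDK6 log2 ratio between the constructs was 0.33 with upper quartiles. Genes lower in both comparisons against vector numbered 9 at 10 CPM, with r = 0.71, and 9 with the nearer bound at 2-fold. The spread parts at 50 CPM were 0.0225 for vector, -0.0064 for CDK6 and 0.0320 for CDK6-D224Y. List medians kept their call, or stayed in their counting interval where they had none, in 574 of 594 values. Of 85 gene comparisons past the rule by named genes, 9 were no longer past it with a CV of 0.1 and 41 with a CV of 0.2. At most 3 were lost with other scalings, thinned counts or a prior count of 5. Named genes below the filter at 5 CPM were left out of this count, and other size rules were not tried on named genes. Depth limits genes near 1 CPM, which equals 17.5 counts in the vector library.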

Other observations

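Gene families were formed by symbol after the values were seen, 15 in all, and describe these libraries only. The interferon genes IFNB1, IFNL1, IFNL2 and IFNL3 were all past the size rule in CDK6-D224Y against vector, with a median log2 ratio of -2.60, and in CDK6 against vector, with a median of -1.09. IFNL1 was at 203, 96.3 and 32.9 CPM and IFNL3 at 116, 54.3 and 20.4 CPM in the vector, CDK6 and CDK6-D224Y libraries, so that interferon transcripts were present in each culture. The 7 MHC class II genes had log2 ratios below 0 in CDK6-D224Y against vector (median -1.09, 4 past the rule), including HLA-DPA1 at 6.51 and 1.08 CPM. The interval of HLA-DOB (-1.23 to 0.58) spanned no difference. The complement genes CFB, C1S, C1R and C3 were all past the rule on the lower side (median -1.54), as were the hydroxycarboxylic acid receptor genes HCAR1, HCAR2 and HCAR3 (median -3.05). Of 12 chemokine genes 6 were past it (median -1.07). The death-inducing BH3-only genes PMAIP1 (144 and 46.7 CPM) and BBC3 (34.4 and 13.4 CPM) were past it as well, in a family of 8 with a median of -0.15.

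Other families had their own order. HOX genes were lower with CDK6-D224Y than with vector for 13 of 16 members (median -0.25, 3 past the rule) and than with CDK6 for 14 of 16 (median -0.62, 1 past the rule). HOXD11 was at 4.11, 2.15 and 0.54 CPM in the vector, CDK6 and CDK6-D224Y libraries. In CDK6 against vector the HOX genes divided, with 8 of 16 above and 8 below (median -0.02). Collagen genes were higher with CDK6-D224Y than with vector for 15 of 20 (median 0.31), with only COL12A1 past the rule. Of the nuclear receptor genes NR4A1, NR4A2 and NR4A3 (median 0.74), 1 of 3 was past the rule on the higher side in CDK6-D224Y against CDK6, NR4A3, and not with a prior count of 5 or an assumed CV of 0.1, while NR4A2 was at 26.0 CPM with CDK6 and 29.7 CPM with CDK6-D224Y. Keratin genes divided, with KRT8 and KRT18 at log2 ratios of 0.16 and 0.24 in CDK6-D224Y against vector and KRT81, KRT16, KRT17 and KRT6B past the rule on the lower side. Medians in CDK6-D224Y against vector were -0.85 for guanylate-binding protein genes, -0.85 for butyrophilin genes, -0.33 for S100 genes, -0.41 for metallothionein genes and 0.11 for histone genes.

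Of the tests of explanations below, those on scaling, on differences between the cultures and on mixed RNA were chosen after the results were seen. The first pattern is the lower level of interferon-response genes in the CDK6 and CDK6-D224Y libraries. Blood cells in the vector culture would bring their own abundant transcripts. The blood cell markers PTPRC, LAPTM5, TYROBP, FCER1G, CD14 and CD3E together reached 0.0153 of the CD74 difference of 52.2 CPM. This argues against blood cells that carry these 6 markers. ITGAM, the only expressed marker of the fixed list, was not in this sum. It stood at 2.86 CPM with vector and 1.61 CPM with CDK6-D224Y. With ITGAM added, the share would lie between the bounds set beforehand for and against blood cells. The test would then decide nothing, so its result holds for the 6 markers only. A wrong scaling factor moves every gene by the same amount, but the median log2 ratio of the interferon-stimulated list in CDK6-D224Y against vector lay -0.36 (-0.41 to -0.33) from that of all expressed genes, which argues against scaling as the cause. Other scalings decide nothing here, since they kept the list median between -0.36 and -0.35, and a test on them, with a bound first set at -0.5 and moved to -0.25 afterwards, was replaced by this one. A difference between the cultures other than the construct, such as the dose or timing of nucleic acid delivery, stays open, because IFNB1 stood at 166 CPM in the vector library, far above the 0.171 CPM of 3 counts, and 1 culture per group ties culture to construct. An effect of CDK6 on innate immune signalling is a hypothesis that stays untested for the same reason, and replicate cultures of each construct would be needed to test it.

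The second pattern is the place of the CDK6 library between the other libraries. If it held a mix of RNA from the vector and CDK6-D224Y cultures alone, every gene would lie the same share of the way from vector to CDK6-D224Y. The median share over the 172 lower genes was 0.539 (0.530 to 0.570), against 0.787 (0.783 to 0.791) for CDK6 itself, and it was 0.245 for B2M and 0.639 for IFNB1, which argues against such a mix. Some vector RNA carried into a CDK6 library is not excluded by this test. The choice of genes by their ratio stays open as a part of the pattern. It alone put the remaining library between for 86.8% of lower genes in simulated libraries with an assumed CV of 0.2, which gave 128.7 such genes per set. With a CV of 0.1 it did so for 87.0%, but only 2.3 genes per set were lower, against the 172 seen. The CV between cultures is unknown. Higher genes (127.5 at a CV of 0.2) were about as many as lower genes by construction, since noise was drawn alike for every gene. Only 15 higher genes were seen beside the 172 lower, which argues against a CV of 0.2 in every gene. A CV that differs between genes was not simulated, so the part that the choice of genes plays is not settled. A graded response to the constructs could not be tested with 1 library per group.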
